A study of Oryza sativa Indica Group with 4 samples.

How the data were processed

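Total RNA from seedlings was extracted with TRIzol, labelled with biotin and hybridised to Affymetrix rice arrays, per the labels' protocols, with 1 array per sample. The deposited values are probe set intensity values on a linear scale, made with GCOS 1.2 per the submitters' processing notes; the signal algorithm and its settings are not given in the sources used here. The mean after trimming 2% of probe sets at each end was 500.1 in all 4 arrays, so each array had been scaled to a common level before it was deposited. No detection calls were used here.

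The 4 arrays fall into 2 wild-type and 2 mutant samples by their labels. The series' design text calls them biological replications, and nothing states shared or separate growth days. From the deposited signals, log2(signal + 16) was taken in R 4.3.3. The 123 AFFX control probe sets were left out, and then the third of probe sets with the lowest mean over the 4 arrays, which removed 19086 and left 38172. The arrays' log2 medians over these lay within 0.06 of each other, under the tolerance of 0.1, so no further normalization was applied. Because of the added 16, log2 differences of dim probe sets are understated.

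Mutant and wild type were compared with limma 3.58.1 (lmFit and eBayes with an intensity trend), with Benjamini-Hochberg adjustment and a threshold of 0.05; every log2 difference is mutant minus wild type, and fold is 2 to the power of its size. The fit was tested on simulated data for this comparison, with 38172 probe sets at the arrays' own levels. Their spread followed signal level alone, smoothed from the within-genotype spread and widened, and noise was independent between probe sets. Of 50 probe sets changed at each size, 34% were recovered at 1.5-fold, 48% at 2-fold, 74% at 4-fold and 96% at 8-fold, with 9 false calls. In the simulated list test 0 of 36 lists were called without an effect, and a list raised by 0.5 was called. Such data suit the intensity trend and hold no correlated genes, so they cannot show how either test fares where spread varies at like signal or genes are correlated.

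Genes were named from the platform's annotation, updated through gene numbers to the RefSeq gene table of assembly ASM3414082v1, a Japonica genome; 22436 probe sets had 1 gene, 95 several and 34850 none listed, and all 22436 matched. Probe sets with several genes were not named. Synonyms of that table can join unlike genes, and neighbours are given in its order. Of 17905 genes, 2449 had an informative name. No gene name in these tables matched OsAPC6, so its transcript was not analysed here.

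The 36 gene lists planned before the data were examined were patterns on gene descriptions, which the tables used here do not carry. They were rewritten as 36 lists on symbols and synonyms after the gene tables were seen and before differences between genotypes were computed; GRF4 in the phosphate list and HSFA2D in the ethylene list were taken out after those differences were seen, as matches through unrelated synonyms. ARD1, which the gene table joins with HSFA2C, was kept in both the ethylene and the heat shock list, where it is 1 of the falls (-0.64). Each list of at least 5 genes, with 1 probe set per gene (the highest mean), was compared with all other genes by limma's camera at a preset correlation of 0.01, with adjustment over the lists; camera with an estimated correlation called 0 of the 36, with 3 at an unadjusted p under 0.05. limma's fry, which tests whether a list's genes move one way without comparing them with other genes, gave an adjusted p under 0.05 for 13 lists, 6 of them among the 8 that camera called. The rest were the lists of G2/M, auxin, brassinosteroid, cellulose and hemicellulose, growth-regulating factors, immune genes, and iron, zinc and metal genes. Hypoxia and redox enzymes, called by camera, did not pass in fry (fry adjusted p = 0.0571 and 0.0796). The sign of the median, the mean and the test differed in lists that camera did not call, such as gibberellin metabolism (median 0.14, mean 0.09, test downward) and abscisic acid (median -0.11, mean 0.06, test downward).

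Counts adjusted over the list alone were 13 up and 1 down for diterpenoid phytoalexins, 10 up and 0 down for chitinases, 19 up and 1 down for jasmonate, 13 up and 3 down for phenylpropanoids, 17 up and 5 down for heat shock, 5 up for hypoxia, 15 up and 6 down for redox enzymes, and 8 up and 2 down for nitrogen. For G2/M genes they were 1 up and 1 down, against 1 and 4 over all probe sets, the one list where they shrank; for auxin 8 and 24, for cytokinin 6 and 12, for cellulose and hemicellulose 3 and 14, and for immune genes 14 and 7. When the planned patterns were applied to symbols as they stood, 8 lists had 5 or more measured genes and 4 passed upward: jasmonate (11 of 17 up; 12 adjusted over the list alone), heat shock and chaperones (11 of 25; 13), pathogenesis-related (3 of 5; 3) and WRKY factors (4 of 6 up and 1 down; 4 and 1). Their camera adjusted p-values were 1.91e-07, 1.39e-05, 0.000379 and 0.0248, and the adjusted p-values with an estimated correlation were 0.142, 0.142, 0.258 and 0.258. The others did not pass: DNA replication (5 genes, none past the threshold; camera adjusted p = 0.63), iron and metal homeostasis (3 up and 3 down of 10; 0.834), phosphate starvation (2 down of 5, 3 adjusted over the list alone; 0.18) and the circadian clock (1 down of 5; 0.159).

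Genes named in the text follow a rule written before the data were examined: the 12 largest rises and 12 largest falls past the threshold with both mutant arrays on the same side of both wild-type arrays and an informative gene name, and in each list the 3 members with the smallest p, or 6 in lists on the cell cycle, gibberellin and the proteasome. The rule's condition on descriptions was read as a condition on names. CYP99A3, KSL4, OsMAS, CYP76M8, CYP71Z6, AOS, GH3.5 and SLR1, here ARD1, and in the closing part PIP1-1, CPS2, CYP76M5 and CYP76M6, fall outside the rule and were chosen after their values were seen. Of 142 genes named by the rule, 119 passed the threshold, and none of those had another called probe set in the opposite direction. MSI1, in the histone list, did not pass at 0.18, while its other probe set was called at -0.37. OsRPN5, in the proteasome list, did not pass at -0.18, while its other probe set was called at -0.50. The second probe set of DTC1, at signals of 24.9 and 28.6, did not pass.

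Alternatives covered quantile normalization, a common 75th percentile, offsets of 1 and 64, the filter, the variance prior, the replicate number as a block, leaving out each array, probe sets that may cross-hybridise, the probe set per gene and the correlation in camera; 2 more, on list members and on the background of the list test, were added after the data were seen. Figures were drawn with matplotlib 3.10.9.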

Results

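Transcript levels were measured in rice seedlings 15 days after germination, in the Indica Basmati cultivar B370 and in a line of it labelled as carrying a T-DNA insertion named for OsAPC6, a subunit of the anaphase-promoting complex, the ubiquitin ligase that moves dividing cells through mitosis. The series held 4 Affymetrix rice arrays, 2 of wild type and 2 of the mutant, each from 8 µg of total RNA. Each array gave 57381 probe set signals, and 62.4% of them in the first wild-type array and 61.9% in the second mutant array lay under 100. Log2 signals correlated at r = 0.98 between the wild-type arrays and at 0.977 between the mutant arrays, across 38172 probe sets, and at 0.963 to 0.964 between genotypes. The median absolute log2 difference was 0.18 between the wild-type arrays, 0.20 between the mutant arrays and 0.34 to 0.35 between genotypes. The transcript of OsAPC6 itself was not analysed here.

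The comparison asked how the seedling transcriptome of the insertion line differed from that of its parent cultivar. The largest rises among genes with an informative name included genes of diterpenoid synthesis, laccases, a chitinase and JAZ2; probe sets without such a name rose further. CYP71Z7, a cytochrome P450 of phytocassane-type diterpenoid synthesis, went from a signal of 207 ± 7.21 (SD, n = 2) to 4162 ± 229.5 (n = 2), a log2 difference of 4.22 ± 0.09 (SE; limma adjusted p = 1.62e-08). DTC1, the diterpene synthase also listed as KSL7, rose from 29.1, a level at which fold is understated, to 727, CPS4, the cyclase that opens the momilactone route, from 51.9 to 1040.05, and the chitinase gene Cht5 from 145.7 to 2094. Among falls of named genes, the nicotianamine synthase gene NAS1 went from 121 to 13.8, near the floor, and fell by 2.29 on the log2 scale with 16 added (SE 0.48, limma adjusted p = 0.00772), PLP2 by 2.23 (SE 0.65, limma adjusted p = 0.0376), with mutant arrays as far apart as 2.3 and 91.0, and the vacuolar iron transporter gene VIT1.2 by 1.95 (SE 0.15, limma adjusted p = 1.63e-05).

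Across the array, 7244 of 38172 probe sets passed a Benjamini-Hochberg adjusted p of 0.05 in limma, 3351 higher and 3893 lower in the mutant. This balance turned with a common 75th percentile, to 3717 higher and 3342 lower, and without either wild-type array. Large changes ran mostly upward: 1132 called probe sets rose and 387 fell by more than 1 on the log2 scale, and 59 rose and 2 fell by more than 3. All 7244 had both mutant arrays on the same side of both wild-type arrays. A call from 2 against 2 arrays largely selects for such separation, so it is no separate support. The number of calls rested on letting the expected variance follow signal level: with a single variance prior limma called 0 probe sets, with 9039 at an unadjusted p under 0.05. A rule without p-values, a fold of at least 2 in the same direction in all 4 pairs of arrays, took 1277 probe sets, 971 higher and 306 lower, of which 1037 were among the 7244.

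Genes of diterpenoid phytoalexin synthesis, which make the antimicrobial momilactones and phytocassanes, moved furthest as a group. Of the 16 measured, 11 rose, 1 fell and 4 did not pass, with a median log2 difference of 2.25. The list was higher than other genes in limma's camera test (adjusted p = 2.29e-08), with adjusted p = 0.364 with an estimated correlation. CPS4, CYP99A2, CYP99A3, KSL4 and the momilactone synthase gene OsMAS, which neighbour each other in the gene order of assembly ASM3414082v1, rose by 3.96, 3.42, 2.67, 2.18 and 2.33. CYP76M7 rose by 3.42 (SE 0.10) and CYP76M8 by 1.74 (SE 0.15). CYP71Z6, next to CYP71Z7 in that order, fell by 0.80 (SE 0.18, limma adjusted p = 0.0126). The 3′ to 5′ signal ratio of the GAPDH control gene, a common measure of RNA integrity, was 9.72 and 9.84 in the wild-type arrays and 18.4 and 16.2 in the mutant arrays. The ratios of actin (16.1 and 8.79 against 12.2 and 16.6) and cyclophilin (2.27 and 2.86 against 2.92 and 2.38) overlapped between genotypes, and those of ubiquitin were 1.04 and 1.03 against 1.32 and 1.27.

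**Figure D1:**
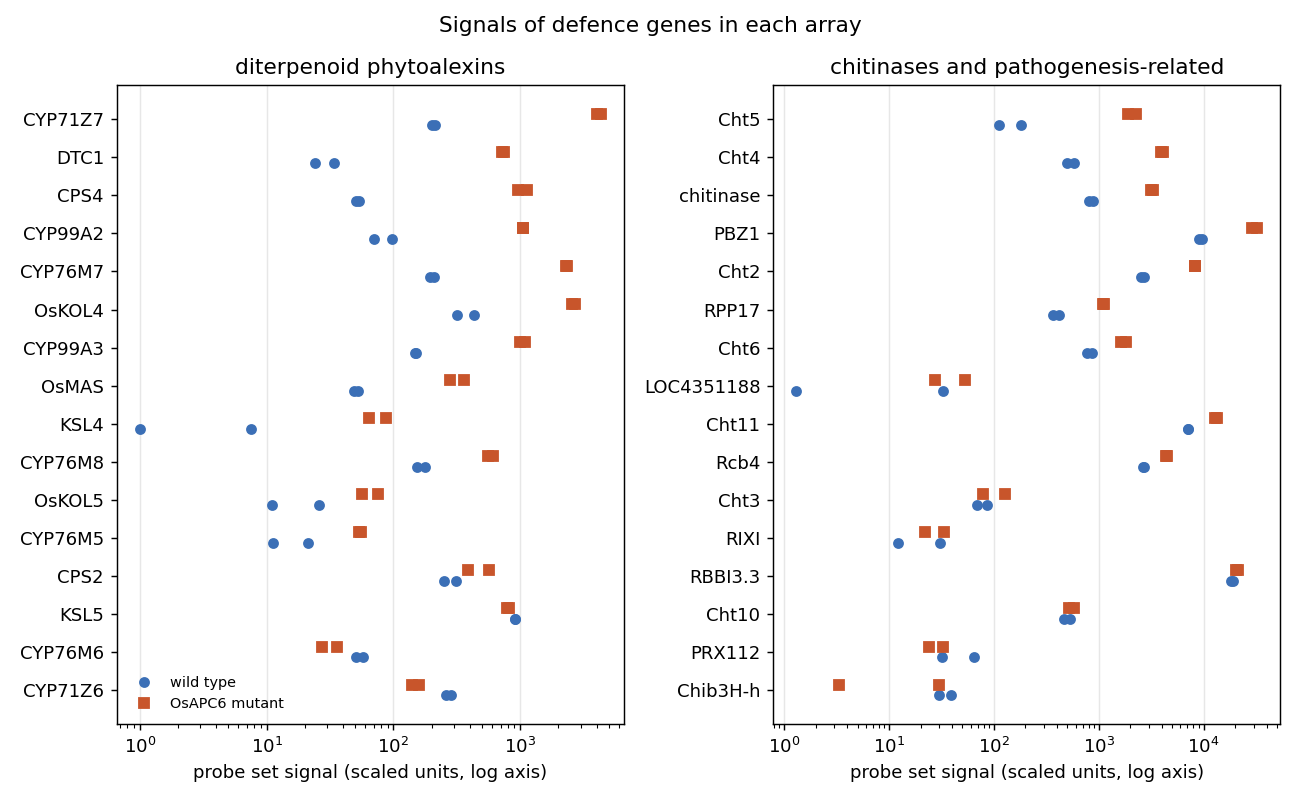
Probe set signals (log axis, scaled units) of the measured members of the diterpenoid phytoalexin list and of the chitinase and pathogenesis-related list, 1 point per array, with circles for the 2 wild-type and squares for the 2 mutant arrays. CYP71Z7 lies at 202.2 and 212.4 in wild type and at 4324 and 3999.5 in the mutant.

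Chitinases and pathogenesis-related genes also rose, 9 of 16 up and 0 down, with a median of 0.90 (camera adjusted p = 8.04e-08; adjusted p = 0.364 with an estimated correlation). Cht4 rose from 539 ± 62.9 to 4022 ± 82.9 (n = 2 each), a log2 difference of 2.87. PBZ1, a pathogenesis-related gene with a wild-type signal of 9405, rose by 1.71. CYP71P1, a P450 of serotonin synthesis, rose by 3.07 (SE 0.09), and the esterase gene Pir7b by 3.32 (SE 0.10). Among immune receptors and regulators 12 of 39 rose, among them MPK13 by 1.22 and NPR4 by 1.28, and 4 fell; the list did not pass (camera adjusted p = 0.119).

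Jasmonate genes rose in 18 of 36 cases and fell in 1, with a median of 0.41 (camera adjusted p = 1.61e-07; adjusted p = 0.364 with an estimated correlation). The lipoxygenase gene LOX9 rose by 2.67 (SE 0.13), and JAZ2 and JAZ11, of the family of repressors that jasmonate itself induces, rose by 3.20 and 1.36. The allene oxide synthase gene AOS rose by 1.92. GH3.5, also listed as the jasmonate-conjugating JAR1, was the member that fell, by 0.62.

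Phenylpropanoid and lignin genes rose in 10 of 27 cases and fell in 2 (median 0.41; camera adjusted p = 0.00215; adjusted p = 0.364 with an estimated correlation). The laccase genes LAC19 and LAC24 rose 11.1-fold and 8.76-fold, from wild-type signals of 47.6 and 41.1, and 4CL5 and CAD2 rose by 2.04 and 1.79. Heat shock proteins and factors rose in 15 of 45 cases and fell in 2 (median 0.18; camera adjusted p = 0.00395; adjusted p = 0.364 with an estimated correlation), led by the small heat shock protein genes HSP18.1 and HSP17.4 at 2.87 (1.89 by another probe set) and 2.82. Of 6 hypoxia genes 4 rose, among them the haemoglobin genes NSHB1 by 1.21 (2.53 and 2.06 by its other probe sets) and NSHB2 by 1.13 (median 1.00; camera adjusted p = 0.00143; adjusted p = 0.364 with an estimated correlation).

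The remaining lists past the threshold were redox enzymes and nitrogen genes. Of all 2290 tested genes with an informative name, 799 had a called probe set, counting every probe set of a gene. The shares called in both lists, at 1 probe set per gene, were not higher. The share called in the heat shock list was close to it. Redox enzymes rose in 14 of 59 cases and fell in 3 (median 0.14; camera adjusted p = 0.0158; adjusted p = 0.737 with an estimated correlation), with APX7 up by 0.86 and GSTU6 by 0.86. This list no longer passed in 6 of 16 alternatives: the estimated correlation, without the first wild-type or the first mutant array, without probe sets ending in _x_at or _s_at, with the mean of all probe sets of a gene, or among genes with an informative name only. Nitrogen uptake and assimilation genes rose in 7 of 25 cases and fell in 1 (median 0.26; camera adjusted p = 0.0285; adjusted p = 0.48 with an estimated correlation), among them the ammonium transporter genes AMT3-2 by 2.10 and AMT1-1 by 0.78 and the glutamine synthetase gene GLN1-2 by 0.92. It no longer passed with the estimated correlation, with quantile normalization, without the first wild-type array or among genes with an informative name only.

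**Figure D2:**
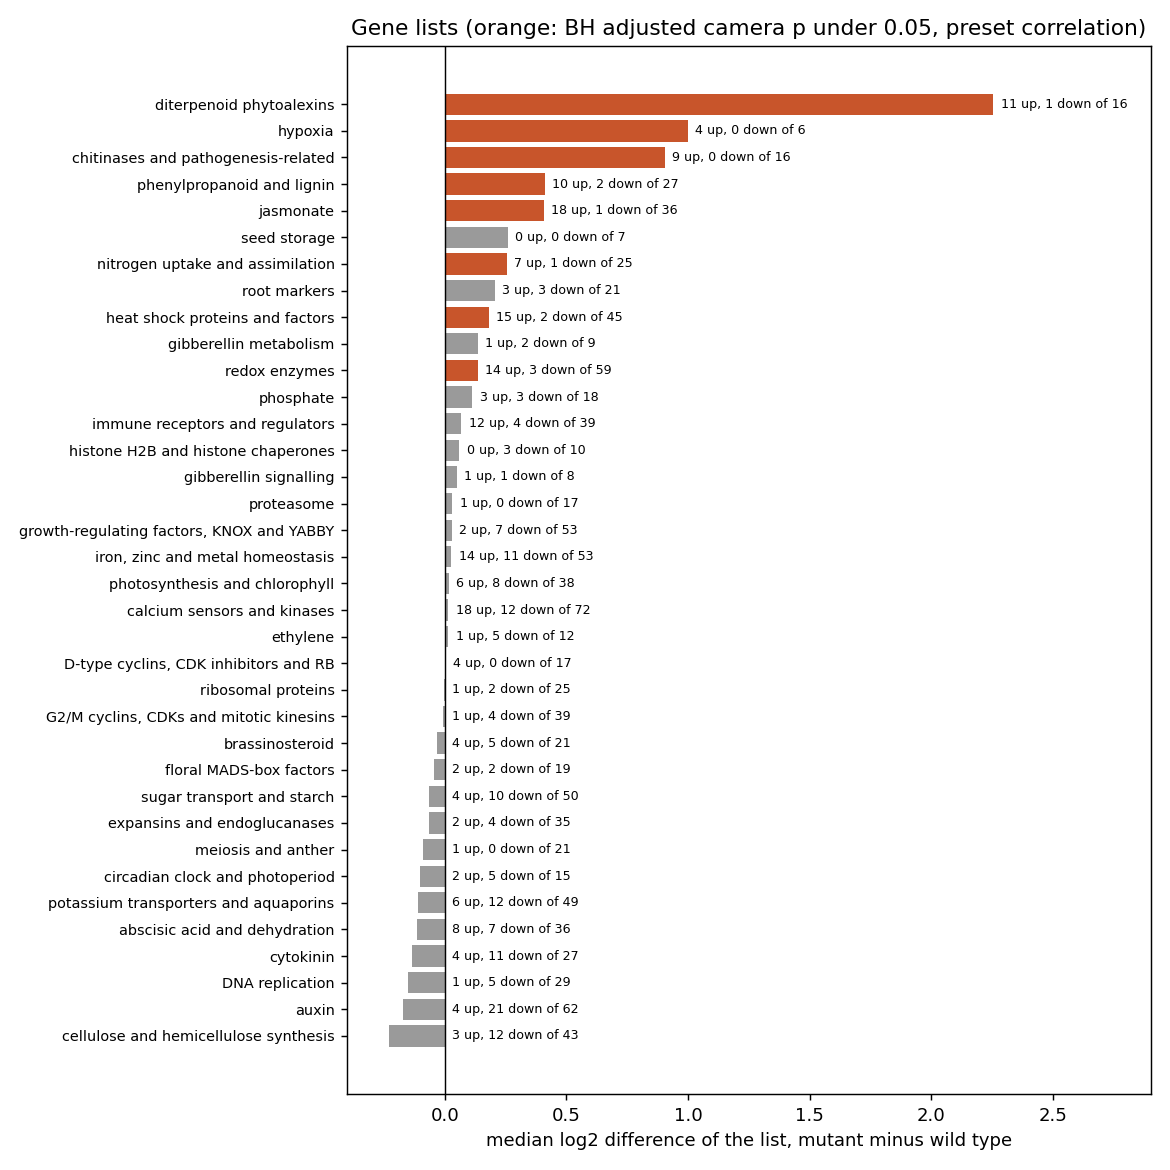
Median log2 difference, mutant minus wild type, of each of the 36 gene lists, with the number of members past the limma threshold beside each bar. Orange bars mark the 8 lists with a camera adjusted p under 0.05 at the preset correlation, all with positive medians, and the longest is that of the diterpenoid phytoalexins at 2.25.

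Plant cell walls are built around cellulose, made by CESA synthases. Of 43 genes of cellulose and hemicellulose synthesis, 12 fell and 3 rose (median -0.23), which did not pass as a list (camera adjusted p = 0.054; adjusted p = 0.576 with an estimated correlation). The secondary wall cellulose synthase genes CESA7, CESA8 and CESA4 fell by 0.75, 0.54 and 0.60 (limma adjusted p = 0.000304, 0.00064 and 0.00248). These falls were no larger than the largest change among 19 rice control probe sets, a fall of 0.77 in a 5′ GAPDH probe set. A part played by RNA integrity was not tested. EXPB2, an expansin gene, went from a dim signal of 85 to 20.9 and fell by 1.47 (SE 0.41, limma adjusted p = 0.032). The pectin methylesterase inhibitor gene PMEI8 fell by 1.64. Among 35 expansin and endoglucanase genes 4 fell and 2 rose (camera adjusted p = 0.833). The YABBY factor gene YAB2 fell by 1.61 (SE 0.10), while the list of growth-regulating, homeobox and YABBY factors had 7 falls and 2 rises among 53 (camera adjusted p = 0.918).

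**Figure D3:**
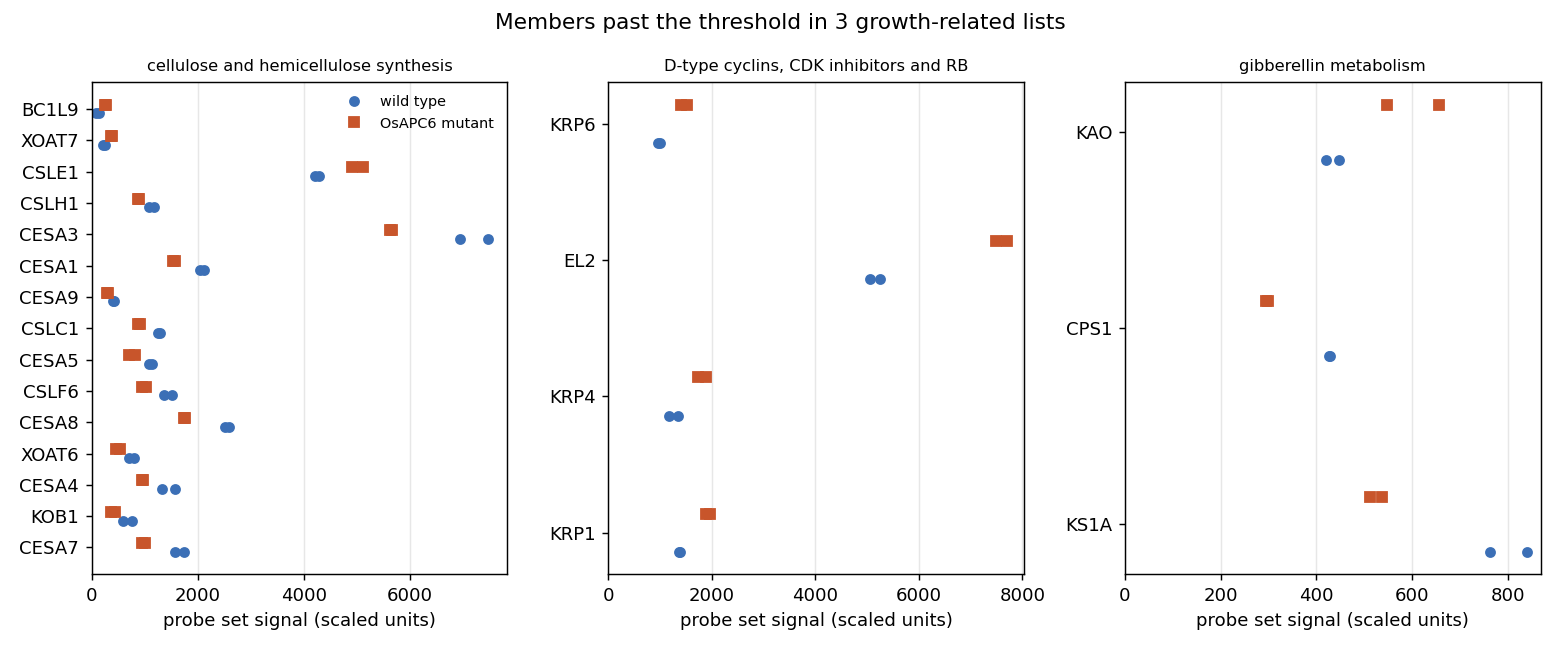
Probe set signals (linear axis from 0, scaled units) of the members past the limma threshold in the lists of cellulose and hemicellulose synthesis, D-type cyclins with CDK inhibitors, and gibberellin metabolism, 1 point per array. CESA7 lies at 1730.5 and 1569.8 in wild type and at 1000.1 and 947.8 in the mutant, and KRP1 at 1362 and 1391 against 1887 and 1961.5.

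Auxin and cytokinin genes had more falls than rises. Among 62 auxin genes 21 fell and 4 rose (camera adjusted p = 0.1). The Aux/IAA genes IAA13 and IAA10 fell by 0.80 and 0.61, and ILL8, of the auxin conjugate hydrolase family, rose by 1.62. Among 27 cytokinin genes 11 fell and 4 rose (camera adjusted p = 0.357): LOGL3, of the cytokinin-activating LOG family, fell by 1.51 from the high signal of 9109 ± 309 (SD, n = 2), while the response regulator gene RR6 rose by 1.66. Brassinosteroid genes split into 4 rises and 5 falls among 21 (camera adjusted p = 0.918), with the inactivating P450 gene CYP734A4 up by 3.03 and its relative CYP734A6 fallen by 1.02. Ethylene genes had 1 rise and 5 falls among 12 (camera adjusted p = 0.69), and abscisic acid and dehydration genes 8 rises and 7 falls among 36 (camera adjusted p = 0.804), with LEA19 up by 2.65.

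The anaphase-promoting complex acts on the cell cycle, and lists close to that function did not pass in camera. In fry, which does not compare a list with other genes, the G2/M list alone among them passed narrowly (fry adjusted p = 0.0494). Among 39 G2/M cyclin, CDK and mitotic kinesin genes 4 fell and 1 rose, and 1 and 1 when adjusted over the list alone (camera adjusted p = 0.833): the kinesin gene KIN14K fell by 1.01 (0.52 by another called probe set) and the A-type cyclin gene CYCA1-4 by 0.32, while KIN7C rose by 0.76. Of 17 genes of D-type cyclins, CDK inhibitors and retinoblastoma proteins, the 4 that rose were all inhibitors, KRP1, KRP4, KRP6 and EL2, by 0.48, 0.52, 0.58 and 0.56 (list camera adjusted p = 0.606). Among 29 DNA replication genes 5 fell, among them RFC2 by 0.38 and ORC2 by 0.41, and FEN1B rose by 0.34 (camera adjusted p = 0.551). Histone H2B and chaperone genes had 3 falls among 10 (camera adjusted p = 0.833), the largest that of H2B.7 by 0.49. Of 17 proteasome genes PBC1 alone passed by the probe set counted, rising by 0.34 (camera adjusted p = 0.833). A dimmer probe set of OsRPN5 was called at -0.50 (limma adjusted p = 0.0325), while the one counted, at -0.18, did not pass. Apart from that of KIN14K, the changes given here were no larger than the largest among 19 rice control probe sets, a fall of 0.77.

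Gibberellin genes did not move as a group. In gibberellin metabolism the early diterpene cyclase genes KS1A and CPS1 fell by 0.60 and 0.50 and the later oxidase gene KAO rose by 0.45, with 6 of 9 genes not past the threshold (camera adjusted p = 0.996). In gibberellin signalling the receptor gene gid1 rose by 0.26 and CIGR2 fell by 0.26, while 6 of 8 genes did not pass (camera adjusted p = 0.918). The DELLA gene SLR1 had a log2 difference of -0.05. None of the changes given here exceeded the fall of 0.77 in a 5′ GAPDH control probe set.

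Photosynthesis and chlorophyll genes had 6 rises and 8 falls among 38 (camera adjusted p = 0.804), the chlorophyll b synthesis gene CAO falling by 0.69 and the regulator gene GLK1 by 0.63. Ribosomal protein genes had 1 rise and 2 falls among 25 (camera adjusted p = 0.996). Of 4 arrays, the 2 per genotype limit the precision of every value. The limma p-values rest on the spread between these samples, with each probe set's variance drawn towards that of others at like signal.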

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

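The tests in this part were chosen after the results were seen.

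A signal outside the rice genes separated the genotypes: the reporter probe set RPTR-Os-K01193-1_at read 10188 on average in the mutant arrays (10386 and 9989) and 245.6 and 287.2 in the wild-type arrays, a log2 difference of 5.18 (SE 0.09, limma adjusted p = 3.12e-09), while no signal of the other 63 reporter probe sets exceeded 78.5 in any of the 4 arrays. The wild-type mean was 2.61% of the mutant mean.

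The rise of the diterpenoid phytoalexin list was weighed against technical explanations. For RNA integrity, the list was set against rice control probe sets. The lower quartile of the 16 members was a log2 difference of 1.04. The largest absolute difference among the 19 rice actin, cyclophilin, GAPDH and ubiquitin control probe sets on the same scale was 0.77, a fall of a 5′ GAPDH probe set. Without the added 16 the lower quartile was 1.51 and the largest control difference 1.07, a fall of a dim GAPDH probe set from 7.15 to 3.40. Most members thus rose by more than any of these controls changed. The list was picked for the size of its rise, and these few control genes set no limit for other transcripts, so RNA integrity stays open. Cross-hybridising probe sets stay open: the 15 members without probe sets ending in _x_at or _s_at had a median of 2.33, but leaving out 1 of 16 could not have brought it under 2.18. A batch of growth, harvest or labelling shared by the arrays of a genotype cannot be told apart from the genotype. Of 62 spike-in probe sets, which hold no plant RNA, 59 (95.2%) separated the genotypes. The 27 hybridisation spike-ins were higher in the mutant arrays (median ratio 1.22) and 32 of 35 poly-A spike-ins lower (0.698). Spike-ins of a kind moved together, so the 33.3% that chance gives a single probe set is no measure for that share. The insertion itself stays among the open explanations, untested.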

How the results depend on the processing

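For probe sets and named genes, the setting that mattered most was the variance prior. Without the intensity trend limma called 0 probe sets and 0 of the named genes, against 7244 and 119, and 9039 probe sets had an unadjusted p under 0.05. The cause was not tested. All 8 lists that camera called kept their call without the trend. With an estimated correlation camera called 0 lists against 8, and the planned patterns, applied after seeing the data, called 4 of 8 lists. The rule of a 2-fold change in all 4 pairs took 1277 probe sets. Leaving out each array in turn, which assumes that the lone sample varies like the other group, gave 5028 to 6498 probe sets, 6 to 9 lists and 100 to 112 named genes. Under the other alternatives run on it, the count lay between 4945 (no filter) and 7661, and no list or named gene past the threshold changed sign under any alternative. The share of calls that were higher in the mutant went from 46.3% to 52.7% with a common 75th percentile and to 52.1% and 52.2% without the first and the second wild-type array, so which direction holds more calls depends on the scaling and on single arrays. The lists of diterpenoid phytoalexins, chitinases, jasmonate, phenylpropanoids, heat shock and hypoxia stayed past the threshold in 15 of 16 alternatives, the exception being the estimated correlation. Redox enzymes did in 10 and nitrogen in 12. These alternatives did not include fry, in which hypoxia and redox enzymes did not pass (fry adjusted p = 0.0571 and 0.0796). Cellulose and hemicellulose synthesis, not past the threshold at 0.054, passed downward in 5 alternatives, with adjusted p-values down to 0.0256 without the second mutant array. With the replicate block, 7661 probe sets, 9 lists and 119 named genes passed. Same-numbered arrays shared no array-wide deviation (r = 3.1e-05 across probe sets). This cannot show whether equal numbers mark a shared growth day or batch. The lowest correlation within a genotype, 0.977, was 0.978 with quantile normalization and 0.977 without a filter. The alternatives planned for the OsAPC6 transcript were not run.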

Other observations

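The tests in this part were chosen after the results were seen, except the gene lists.

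Metal, potassium and calcium genes changed in both directions. Of 53 iron, zinc and metal genes 14 rose and 11 fell (camera adjusted p = 0.564). Within the iron acquisition route, NAAT1, which makes a precursor of the iron chelator deoxymugineic acid, rose by 1.93 (SE 0.07), while the chelator's transporter gene YSL15 fell by 1.62 (SE 0.25) and NAS1 by 2.29; the metallothionein genes MT1B and MT4A rose by 2.03 and 0.98. Among 49 potassium transporter and aquaporin genes 6 rose and 12 fell (camera adjusted p = 0.833): HAK1, HAK16 and HAK17 rose by 1.70 (0.83 by another called probe set), 1.24 and 1.13, and the aquaporin gene PIP1-1 fell by 0.93. Of 72 calcium sensor and kinase genes 18 rose and 12 fell (camera adjusted p = 0.804), with CML14 up by 2.22, CIPK21 up by 1.98 and CIPK5 down at -1.19. Phosphate genes had 3 rises and 3 falls among 18 (camera adjusted p = 0.788), with the transporter genes PHT1-1 and PHT1-8 up by 0.77 and 0.97. Sugar transport and starch genes had 4 rises and 10 falls among 50 (camera adjusted p = 0.297), SWEET14 falling by 1.07 and SUS1 by 0.76 (1.30 by another called probe set).

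Lists that watch for unlike tissue or harvest time did not pass in camera. That test looks for a shift in 1 direction, so it cannot exclude a difference in harvest time that moved clock genes both ways. Root markers had 3 rises and 3 falls among 21 (camera adjusted p = 0.69), the silicon transporter genes Lsi1 and Lsi6 falling by 0.74 and 0.81; several of these genes also stand in the nutrient lists. Clock and photoperiod genes had 2 rises and 5 falls among 15 (camera adjusted p = 0.469), with PCL1 up by 0.97, and Ehd3 and phyC fallen by 0.69 and 0.56. Floral MADS-box genes had 2 rises and 2 falls among 19 (camera adjusted p = 0.996), meiosis and anther genes 1 rise among 21 (camera adjusted p = 0.918), which was DTC1 of the phytoalexin list, and none of 7 seed storage genes passed (camera adjusted p = 0.804).

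A hypothesis on gene position was that strongly raised genes lie side by side. Raised here meant past the limma threshold with a log2 difference above 1. Among 16488 measured genes in the order of assembly ASM3414082v1, 550 were raised. They formed 46 neighbouring pairs, against a median of 18 and a highest value of 30 in 1000 shuffled orders. The 139 genes past the threshold that fell by more than 1 formed 2 such pairs, against a median of 1 in shuffled orders. Cross-hybridisation between neighbouring copies stays open: the order of 15485 genes without probe sets ending in _x_at or _s_at held 45 such pairs, where shuffled orders reached 32, but only 8 of the 46 pairs held such a probe set. The 5 momilactone genes from CPS4 to CYP99A2 held 5 consecutive places and were all raised. In the run from CYP76M5 to CYP76M6, with 8 listed genes, only CYP76M8, DTC1 and CYP71Z7 were raised in this sense. CYP76M5 had a log2 difference of 1.15 but did not pass the threshold. CPS2 had a log2 difference of 0.72 and CYP71Z6 of -0.80, both smaller in size than 1. Control shared between neighbours may account for neighbouring raised pairs but was not tested.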
